A study of Mus musculus with 6 samples.

How the data were processed

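RNA from the tibialis anterior muscle of mdx mice and of mdx mice lacking miR-206 was measured on 6 single-colour Illumina bead arrays, 3 per genotype, at 3 months of age. The mdx mouse carries a mutation in the dystrophin gene and is a model of Duchenne muscular dystrophy, and miR-206 is a microRNA made mainly in skeletal muscle. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase treatment, checked on a Bioanalyser, and amplified into Cy3-labelled cRNA with an Ambion kit. The scanner and its software are not given in the sources used here.

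The authors deposited, for each of 45281 probes and each array, the mean bead intensity on a linear scale with no normalization visible in the values, the number of beads, the standard error over beads and a detection p-value. Per the file headers these are per-array columns, and the deposited detection p-values lie on steps of 1 in 936, the form they take when each probe is ranked against that number of negative control probes. Control probes were not analysed here. A second table by the authors holds intensities of the same arrays after quantile normalization: each column has the same probe ranks as its own array (Spearman correlation 1, against at most 0.841 with another array). Its column medians lie between 104.957 and 105.022, so its scale is linear and it carries no centring per gene. No method was named for it in the sources used here, and it served only as an alternative.

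Array depth was similar. Each probe was read by a median of 41 to 42 beads, and the median standard error over beads was 4.75% to 6.14% of the intensity among detected probes. Between 16741 and 18561 probes per array had a detection p-value under 0.05, and the median raw intensity ran from 96.7 to 118.25. The number of arrays limits the precision of every comparison.

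Probes were named through the platform annotation supplied with the series: 34885 probes had 1 gene symbol, 18 had several and were not named, and 10378 were not listed and stayed unnamed. Gene IDs of 34807 of the named probes matched a reference gene table (assembly GRCm38.p6), and 0 symbols changed. That table was used only for names, chromosomes and the order of genes. Several list members therefore had no named probe.

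Background was corrected with limma's neqc (limma 3.58.1 in R 4.3.3), which fits a normal-exponential model with the background inferred from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept (17263 probes, 14836 of them with 1 gene), and each of 9784 genes was represented by its brightest kept probe. The genotypes were compared with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjustment over genes, with calls at an adjusted p under 0.05. Fold changes are miR-206 KO mdx minus mdx on the log2 scale, which the offset pulls towards 0 for dim probes. A probe not detected on any array of a group has only a bound there. It is given as the bright group's mean against, per array of the dim group, the higher of the lowest normalized value among detected probes and the probe's own value. The bound holds only under this processing, since the background correction sets its size.

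Gene lists for cell types and pathways of dystrophic muscle (32 lists) were fixed before the data were examined, and 29 were tested with camera at a preset correlation between genes of 0.01, two-sided, adjusted over lists with at least 5 measured genes. A list score is the mean, over its genes, of the deviation of each array from the gene's mean over the 6 arrays. Scores were compared with two-sided exact permutation tests, whose smallest p for 3 arrays against 3 is 0.1. Named genes also followed a rule fixed beforehand. It takes up to 12 called genes per direction with groups that do not overlap. Where fewer are called, it fills up to 12 from genes at an unadjusted p under 0.01 with groups that do not overlap, as values that did not pass. It adds up to 4 members per list with the smallest p, and a set of reported miR-206 targets, Dmd and sex-linked genes as values.

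The fit was tested on simulated data for this comparison of 9784 genes, with 200 genes changed in each of 20 draws and each gene's spread drawn from the distribution that limma estimated on the arrays. The share recovered was 5% at 1.5-fold, 49.5% at 2-fold, 95.2% at 4-fold and 99.4% at 8-fold, and 5.02% of calls were false. Genes were simulated as independent and all folds were planted together. The shares may therefore not hold on arrays where genes vary together or fewer genes change. These shares depend on how spread is drawn: with each gene's moderated variance, the form tried first and replaced after its shares were seen because such variances differ less between genes, they were 12.5%, 74.4%, 99.6% and 99.9%, with 5.32% of calls false. In simulated lists of 25 genes with no effect, camera at the preset correlation called 2% of lists when genes were independent, 21% at a true correlation of 0.1 and 63% at 0.6. With an estimated correlation it called 0%, 1% and 3%.

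Alternatives were the authors' normalized table, no background correction, median centring, no detection filter, a stricter filter, the title number as a block, each array left out, a variance trend with robust fitting, array weights, the mean over a gene's probes, all probes in place of genes, other thresholds, an estimated correlation and fry. A test of miR-206 seed sites was planned and not run, because 3' UTR sequences were not used here. A slide block was not run, because no slide is given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.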

Results

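Messenger RNA of the tibialis anterior, a fast hindlimb muscle, was profiled in 3 mdx samples and 3 mdx samples with miR-206 deleted (miR-206 KO mdx), all on a mixed C57BL/6/129Svev background at 3 months of age. The labels number the samples within each genotype, and where these are not separate animals the p-values measure only technical spread. Between 36.97% and 40.99% of probes were detected per array. The median SD over genes was 0.19 log2 units within mdx and 0.22 within miR-206 KO mdx (n = 3 each). The comparison asks how loss of miR-206 alters gene expression in dystrophic muscle, as the series title frames it. No probe of the annotation used here names miR-206, so its absence could not be checked on these arrays.

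The largest median shift among the called lists was in macrophage and monocyte genes, which were higher in miR-206 KO mdx muscle. Of 25 measured genes 24 had a positive log2 fold change, with a median of 1.02, and the list passed camera at the preset correlation (adjusted p = 1.3e-16). The adjusted p was 0.48 with an estimated correlation, which was 0.61 among these genes. Mpeg1, a macrophage pore-forming protein, was at 9.10 ± 0.55 in mdx and 10.32 ± 0.21 in miR-206 KO mdx (SD, n = 3). Adgre1, a macrophage surface receptor gene, was at 8.04 ± 0.54 and 9.17 ± 0.39, and C1qb, a subunit of complement C1q, at 8.21 ± 0.85 and 9.59 ± 0.27. Ms4a7 was at 7.31 ± 0.76 in mdx and 8.69 ± 0.45 in miR-206 KO mdx. None of the 25 genes passed over all genes, and 15 passed when adjusted over the list alone. The list score was -0.49 ± 0.49 in mdx and 0.49 ± 0.59 in miR-206 KO mdx (SD, n = 3; exact permutation p = 0.2), and mdx sample 1, at -0.01, lay above miR-206 KO mdx sample 2, at -0.15.

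Extracellular matrix and fibrosis genes were also higher in miR-206 KO mdx: 24 of 26 had a positive log2 fold change, with a median of 0.61 (camera adjusted p = 1.6e-09, and adjusted p = 0.48 with an estimated correlation). Tnc, which encodes the matrix glycoprotein tenascin C, was at 7.22 ± 0.36 in mdx and 8.30 ± 0.07 in miR-206 KO mdx. Col8a1, a collagen chain, was at 8.06 ± 0.16 and 8.86 ± 0.26, and Loxl1, a lysyl oxidase-like enzyme, at 10.23 ± 0.30 and 10.96 ± 0.01. These were the 3 genes of the list that passed when adjusted over the list alone, and 0 passed over all genes. The groups overlapped in list score (exact permutation p = 0.2): mdx sample 1, at 0.21, lay above miR-206 KO mdx sample 2, at -0.01. The median log2 fold change was 0.33 without mdx sample 2. The fibro-adipogenic progenitor list holds markers of the stromal cells that give rise to fibroblasts and fat cells in muscle. Its median was 0.07 over 14 genes (camera adjusted p = 0.66, and adjusted p = 0.89 with an estimated correlation). This value rested on single samples: the list passed, with a median of 0.41, without mdx sample 1 and, with a median of 0.28, with array weights, and its median was -0.12 without mdx sample 2.

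Genes of regenerating myofibres were higher in miR-206 KO mdx, with a positive log2 fold change in 12 of 15 and a median of 0.59 (camera adjusted p = 5.6e-05, and adjusted p = 0.48 with an estimated correlation). Myh8, the perinatal myosin heavy chain, was at 11.51 ± 0.46 in mdx and 12.77 ± 0.90 in miR-206 KO mdx. Myl4, an embryonic myosin light chain, was at 12.21 ± 0.33 and 13.23 ± 0.81, and Ncam1, a cell adhesion molecule of regenerating and denervated fibres, at 7.60 ± 0.59 and 8.39 ± 0.21. Without miR-206 KO mdx sample 2 the median was 0.36. All 23 cell cycle genes had a positive log2 fold change, with a median of 0.23 (camera adjusted p = 1.8e-05, and adjusted p = 0.48 with an estimated correlation). The groups overlapped in the cell cycle score (exact permutation p = 0.2), with mdx sample 2 at -0.04 and miR-206 KO mdx sample 2 at -0.08, and in the regenerating myofibre score mdx sample 1 and miR-206 KO mdx sample 3 both lay at -0.02 (exact permutation p = 0.1, the smallest possible). Cdca8, a subunit of the chromosomal passenger complex, was at 5.12 ± 0.26 in mdx and 5.80 ± 0.19 in miR-206 KO mdx. Stmn1, a microtubule regulator, was not above background on any mdx array. Satellite cell and myoblast genes had a median of 0.24 over 9 genes (camera adjusted p = 0.11, and adjusted p = 0.48 with an estimated correlation). Myod1 was at 7.05 ± 0.33 and 7.45 ± 0.32. That list passed with median centring (median 0.22, adjusted p = 0.047) and without miR-206 KO mdx sample 3 (0.25, adjusted p = 0.048), and its median was 0.39 without mdx sample 1, 0.09 without miR-206 KO mdx sample 1 and 0.02 without the detection filter. No gene of these 3 lists passed over all genes or when adjusted over the list alone.

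Another 4 lists were called at the preset correlation of 0.01. The estimated correlation was 0.86 for MHC class II, 0.35 for interferon, 0.04 for unfolded protein response and 0.02 for citrate cycle genes. For the lists above it was 0.47 for matrix, 0.18 for regenerating myofibre and 0.15 for cell cycle genes. In simulated lists with no effect the preset called 21% at a true correlation of 0.1 and 63% at 0.6. MHC class II genes had positive log2 fold changes in 6 of 6, with a median of 0.61 (camera adjusted p = 0.00051, and adjusted p = 0.57 with an estimated correlation). The groups overlapped in list score (exact permutation p = 0.3): mdx sample 1, at 0.35, lay above miR-206 KO mdx samples 2 and 3, at 0.11 and 0.13. That median was 0.40 without mdx sample 2 and 0.96 without mdx sample 1. Interferon response genes had a median of 0.25, with 14 of 15 positive (camera adjusted p = 0.0096, and adjusted p = 0.64 with an estimated correlation). In their score mdx sample 1, at 0.20, also lay above miR-206 KO mdx samples 2 and 3, at -0.03 and -0.05 (exact permutation p = 0.4). Their call was lost without mdx sample 2, mdx sample 3 or miR-206 KO mdx sample 1, with medians of 0.17, 0.16 and 0.18, and the median was 0.45 without mdx sample 1. Unfolded protein response genes had a median of 0.13 over 15 genes (camera adjusted p = 0.036, and adjusted p = 0.48 with an estimated correlation). Asns, asparagine synthetase, was at 7.51 ± 0.40 in mdx and 8.33 ± 0.04 in miR-206 KO mdx. In the list score mdx sample 1, at -0.03, lay above miR-206 KO mdx sample 2, at -0.06 (exact permutation p = 0.2). That call was lost without mdx sample 2, mdx sample 3, miR-206 KO mdx sample 1 or miR-206 KO mdx sample 3, with medians of 0.13, 0.19, 0.10 and 0.17, and the median was 0.22 without miR-206 KO mdx sample 2. Citrate cycle and fatty acid oxidation genes were the 1 list lower in miR-206 KO mdx, with negative values in 25 of 27 and a median of -0.12 (camera adjusted p = 0.0096, and adjusted p = 0.48 with an estimated correlation). Fabp3, the heart and muscle fatty acid binding protein, was at 13.19 ± 0.13 and 12.82 ± 0.16, and the call was lost without mdx sample 2, with a median of -0.09. No gene of these 4 lists passed over all genes or when adjusted over the list alone. The macrophage, matrix, MHC class II and interferon scores shared a pattern over the arrays. In each, mdx sample 1 was the highest and mdx sample 2 the lowest mdx sample, and miR-206 KO mdx sample 1 was the highest of its group. These lists may therefore reflect a shared difference between samples and are not separate evidence.

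**Figure D1:**
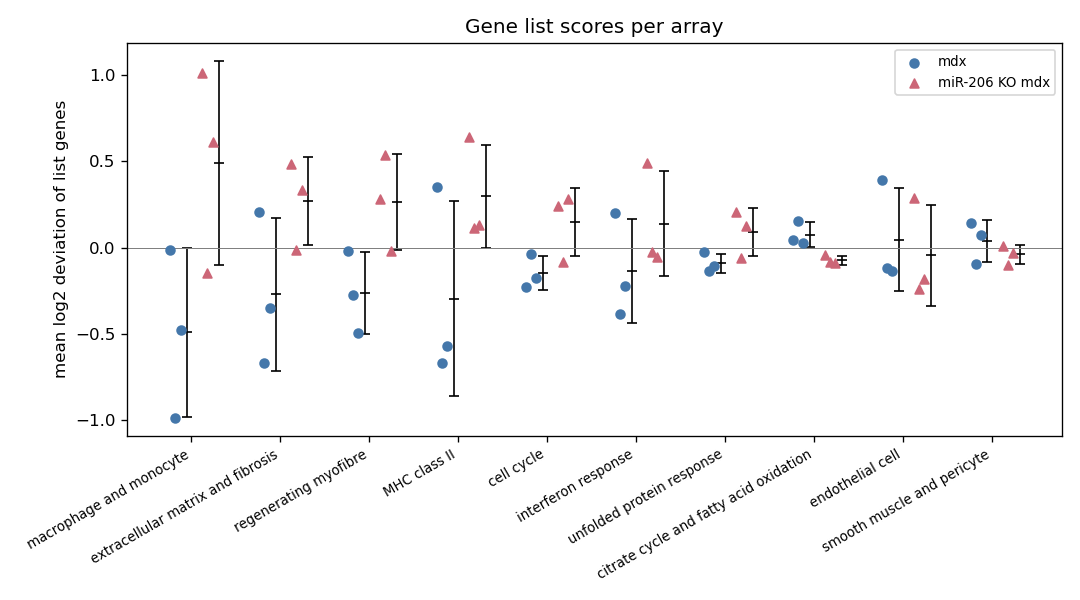
Mean log2 deviation of the genes of 10 lists (vertical axis, log2 units) on each array, with circles for mdx, triangles for miR-206 KO mdx, and black bars for the mean and SD of 3 arrays. The macrophage score ranges from -0.99 to -0.01 in mdx and from -0.15 to 1.01 in miR-206 KO mdx.

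The remaining 21 tested lists did not pass under the processing chosen, and 9 of them passed under at least 1 alternative. Granulocyte and mast cell genes had a median log2 fold change of 0.72 over 6 genes (camera adjusted p = 0.11, and adjusted p = 0.64 with an estimated correlation). With all 6 arrays they passed with median centring (median 0.68, adjusted p = 0.027), the replicate block (adjusted p = 0.032) and array weights (median 1.13, adjusted p = 0.0098). They also passed without mdx sample 1 (1.29) or miR-206 KO mdx sample 2 (1.05). Their median was 0.29 with the authors' table and 0.25 without background correction, and 0.24 without mdx sample 2, 0.42 without mdx sample 3, 0.26 without miR-206 KO mdx sample 1 and 0.48 without miR-206 KO mdx sample 3. Oxidative phosphorylation genes had a median of -0.08 over 31 genes (camera adjusted p = 0.13, and adjusted p = 0.64 with an estimated correlation). Their median was -0.05 without miR-206 KO mdx sample 1 (adjusted p = 0.40) and -0.13 without mdx sample 3 (adjusted p = 0.052). With all 6 arrays they passed with the authors' table (adjusted p = 0.038), without background correction (adjusted p = 0.028), with median centring (median -0.21, adjusted p = 6.2e-05) and with a variance trend (adjusted p = 0.019), and they passed without miR-206 KO mdx sample 3 (adjusted p = 0.029). The drop with median centring was not particular to them. Glycolysis genes went from 0.00 to -0.21 and fast fibre genes from 0.04 to -0.17, and the median over all genes was -0.06. Ribosomal protein genes, with a median of 0.11 over 18 genes (camera adjusted p = 0.15), passed with the authors' table (adjusted p = 0.048), without background correction (adjusted p = 0.035), with a variance trend (adjusted p = 0.029), with the mean over probes (adjusted p = 0.041) and without miR-206 KO mdx sample 2 (adjusted p = 0.046). Their median was -0.06 with median centring and 0.06 without miR-206 KO mdx sample 1 (adjusted p = 0.42). With an estimated correlation their camera adjusted p was 0.64.

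Medians of several other lists turned sign when 1 array was left out. That of endothelial genes was -0.11, from -0.26 without miR-206 KO mdx sample 1, where the list passed, to 0.07 without mdx sample 1. Adipocyte genes were at -0.10, from -0.26 without mdx sample 2 to 0.08 without miR-206 KO mdx sample 2. Schwann cell genes were at 0.14, from -0.20 without mdx sample 2 to 0.45 without mdx sample 1, and tendon genes at 0.10, from -0.03 without mdx sample 2 to 0.28 without miR-206 KO mdx sample 2. Immediate early genes were at 0.16, from -0.09 without miR-206 KO mdx sample 1 to 0.23 without miR-206 KO mdx sample 3, where the list passed. Atrophy and proteasome genes were at 0.04, from -0.03 without mdx sample 1 to 0.10 without mdx sample 2. Over the arrays left out, glycolysis genes (0.00) ran from -0.05 to 0.04 and Notch pathway genes (-0.02) from -0.03 to 0.04. The sign held when any 1 array was left out for smooth muscle and pericyte genes at -0.08 (-0.14 to -0.05), dystrophin complex genes at -0.05 (-0.12 to -0.02), neuromuscular junction genes at 0.09 (0.00 to 0.19), IGF and myostatin pathway genes at 0.02 (0.02 to 0.17) and fast fibre genes at 0.04 (0.02 to 0.06). The fast fibre median was -0.17 with median centring. Slow fibre genes had a median of 0.32, which was 0.14 without miR-206 KO mdx sample 1, 0.13 without miR-206 KO mdx sample 2, and 0.72 without miR-206 KO mdx sample 3, where the list passed. Within the slow fibre list Tnnt1, slow troponin T, was at 10.24 ± 0.42 in mdx and 11.50 ± 0.92 in miR-206 KO mdx, while Myl2, the slow myosin regulatory light chain, was at 10.40 ± 0.76 and 9.04 ± 1.60. The 3 lymphocyte genes and 4 erythroid genes were too few to test, with medians of 0.19 and -1.02. Without the detection filter the erythroid list had 6 genes and was called lower, with a median of -0.99 (camera adjusted p = 0.0036). The erythroid score, which includes near-identical globin copies, ran from -0.37 to 1.70 in mdx and from -1.84 to 0.35 in miR-206 KO mdx.

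Reported targets of miR-206 and of miR-1, which shares its seed, had a median log2 fold change of 0.14 over 17 genes, with 12 positive. The camera adjusted p was 0.28, and 0.75 with an estimated correlation. The median was 0.00 without miR-206 KO mdx sample 1, 0.05 without mdx sample 2, 0.06 without miR-206 KO mdx sample 3 and 0.07 without mdx sample 3, and the list passed, with a median of 0.17, without miR-206 KO mdx sample 2. Fstl1 was at 9.15 ± 0.61 in mdx and 9.61 ± 0.43 in miR-206 KO mdx, a log2 fold change of 0.45 (adjusted p = 0.86). That value was 0.24 without mdx sample 3, 0.29 without miR-206 KO mdx sample 3, 0.70 without miR-206 KO mdx sample 2 and 0.80 without mdx sample 1. Igfbp5 had a log2 fold change of 0.19, Notch3 of -0.10, Hdac4 of -0.06 and Gja1 of 0.04, none of which passed. Over the arrays left out Igfbp5 ran from 0.02 without miR-206 KO mdx sample 2 to 0.33 without miR-206 KO mdx sample 3, Notch3 from -0.23 to 0.00, Hdac4 from -0.26 to 0.07 and Gja1 from -0.09 to 0.19. Pax7 and Pola1 were not above background on any array. Utrn and Dmd, which encode utrophin and dystrophin, stayed below the detection filter on all of their 5 and 3 probes. Utrn was detected on miR-206 KO mdx arrays only, by separate probes on 2, 1 and 2 arrays. Their log2 fold changes were 0.52, 0.33 and 0.28, near the floor and not tested. The remaining Utrn probes, at -0.01 and 0.16, and those of Dmd were detected on no array. Xist was detected on all 6 arrays, at 10.39 ± 0.05 in mdx and 10.80 ± 0.06 in miR-206 KO mdx (adjusted p = 0.64). Its other probes disagree in direction, with log2 fold changes of 0.39, -0.10 and -0.42, and of the Y-linked genes Kdm5d and Eif2s3y were not detected on any array. The third, Uty, was detected by 1 of its 4 probes, on 2 mdx arrays and 1 miR-206 KO mdx array. Its log2 fold change was -0.29 (adjusted p = 0.86), and ran from -0.47 to -0.18 over the arrays left out. The Uty values, from 4.45 to 5.18, lay near the floor, since the lowest values of detected probes were 4.88 to 5.05 over the arrays. No Y-linked difference can be read from them.

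No single gene passed the test over all 9784 genes with limma (0 genes, smallest adjusted p = 0.62), and 0 passed when all detected probes were tested. At an unadjusted p under 0.05 there were 662 genes, 406 higher and 256 lower, where 489 would be expected by chance. In 10.7% of genes the 2 groups did not overlap, against 10% by chance. The values that follow did not pass. The lowest log2 fold change among the named genes was that of Kcnq5, a voltage-gated potassium channel gene. Its brightest probe was detected on 3 of 3 mdx arrays, at 7.13 ± 1.09, and on 0 of 3 miR-206 KO mdx arrays. Under the processing chosen, the signal of that probe was at least 4.5-fold lower (adjusted p = 0.62). The other 2 Kcnq5 probes were detected on 1 and 0 mdx arrays, with log2 fold changes of -0.27 and 0.03 near background. The bound therefore holds for 1 probe and was not seen with the others. Kcnq5 lies on chromosome 1, as does the miR-206 gene, with 25 annotated genes between them. It was the 1 gene of 25 measured flanking genes that passed when adjusted over the list alone (median log2 fold change of the list -0.01, camera adjusted p = 0.76). Klk1b22, 1 of a family of near-identical kallikrein genes, was detected on all 3 mdx arrays and on no miR-206 KO mdx array. Under the processing chosen Klk1b22 was at least 2.29-fold lower and Ptpn9, a tyrosine phosphatase gene, at least 1.35-fold lower. Without background correction the log2 fold changes were -1.18 for Kcnq5, -0.70 for Klk1b22 and -0.27 for Ptpn9, all smaller than these bounds.

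Psmd8, a subunit of the 26S proteasome, was at 9.24 ± 1.38 in mdx and 11.63 ± 0.23 in miR-206 KO mdx (adjusted p = 0.62). Without mdx sample 3 it was the 1 gene that passed, with a log2 fold change of 3.19 (adjusted p = 0.0073, the lowest of its alternatives, which reached 0.9997). Its second probe was detected on 1 array. Pvr, the poliovirus receptor gene, was at 5.07 ± 0.99 in mdx and 6.78 ± 0.31 in miR-206 KO mdx, and was detected on 1 of 3 mdx arrays. Its log2 fold change of 1.71 was 0.75 with the authors' table and 0.67 without background correction, and its second detected probe had 0.99. Other named genes with higher values were Apoe, a lipid carrier, with a log2 fold change of 1.36, and Ms4a7 with 1.39, as well as Capn6 with 1.29, Fcer1g with 1.25 and Ifi30 with 1.17. The second detected probe of Ifi30 had a log2 fold change of 0.18 and that of Ms4a7 0.44, and the means over detected probes were 0.67 and 0.92. Apoe was at 0.85 without mdx sample 2. Under the processing chosen Sirpb1a was at least 1.67-fold higher and Tceal3 at least 1.67-fold higher. Both are members of families with near-identical copies and were not above background on any mdx array. Without background correction the log2 fold changes were 0.79 for Capn6, 0.74 for Ifi30, 0.47 for Sirpb1a and 0.43 for Tceal3. The values for Sirpb1a and Tceal3 were smaller than their bounds. Nfkbib, an inhibitor of NF-kappa-B, was at 6.18 ± 0.21 in mdx and 5.18 ± 0.11 in miR-206 KO mdx, and Ctcfl at 6.48 ± 0.51 and 5.49 ± 0.35. Lower values were also seen for 3300002P13Rik at -1.40, Pcid2 at -1.05, Ptov1 at -0.96, Pln, phospholamban, at -0.93, Plin5, a lipid droplet protein of oxidative tissue, at -0.89, Dusp18 at -0.89 and Prpf31, a splicing factor, at -0.83. Most of these lower values shrank by over 1.5 times without background correction, to -0.34 for Nfkbib, -0.40 for Ctcfl, -0.90 for 3300002P13Rik, -0.42 for Pcid2, -0.31 for Ptov1, -0.34 for Pln, -0.48 for Dusp18 and -0.46 for Prpf31. Ptov1 was detected on 1 of 3 miR-206 KO mdx arrays, and Pcid2 and Pln on 2, and the second detected probe of Plin5 had -0.35. Of the 3 Prpf31 probes 1 was detected, and the others, below background on every array, had -0.07 and 0.14.

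**Figure D2:**
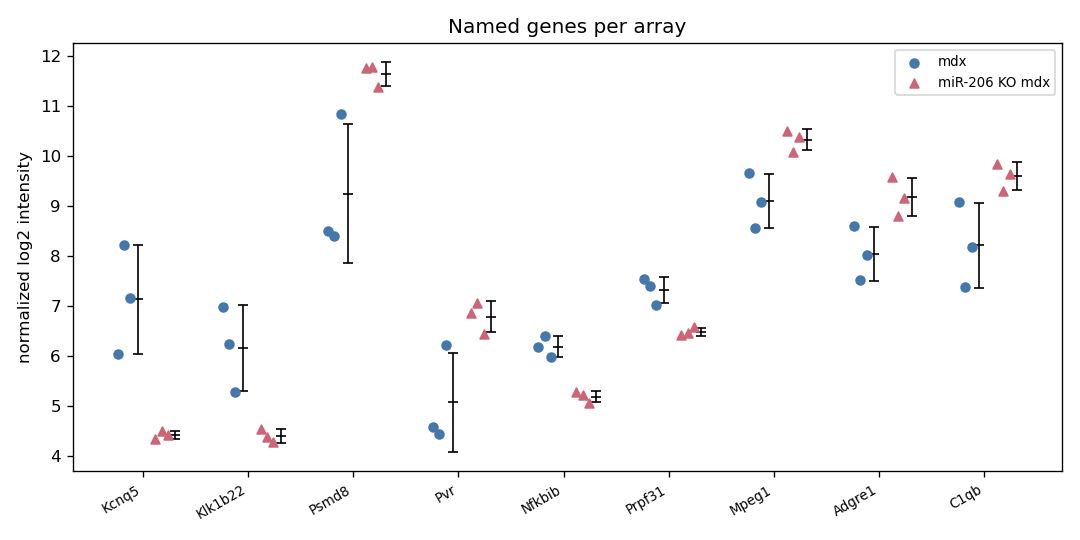
Normalized log2 intensity (vertical axis) of 9 named genes on each array, with circles for mdx, triangles for miR-206 KO mdx, and black bars for the mean and SD of 3 arrays. The groups do not overlap for any of the 9 genes, because the rule for naming genes required it. Psmd8 in mdx sample 3 lies at 10.84, between 8.39 and 8.50 in the other mdx samples and 11.37 to 11.78 in miR-206 KO mdx.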

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

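The count of genes at an adjusted p under 0.05 was 0 with the authors' normalized table, without background correction, with median centring, with either other filter, with a variance trend, array weights, the mean over probes, all detected probes, and at an adjusted p under 0.1. Leaving out each array gave 0 to 1 genes, with Psmd8 the 1 gene without mdx sample 3. At an unadjusted p under 0.05 the count was 662, and 289 with a fold of at least 1.5 as well. The count of called lists was 8, between 8 and 11 under the alternatives of normalization, filter, variance, weights and probe choice, and 5 to 11 when each array was left out, with 5 without mdx sample 2. It was 0 with an estimated correlation and 0 with fry, both of which allow for correlation among the genes of a list. Whether title numbers pair the samples is unclear. Deviations of same-numbered arrays from their group means correlated at 0.18, 0.22 and -0.08. Those of differently numbered arrays ran from -0.29 to 0.17. With the replicate block 0 genes and 9 lists were called, granulocyte and mast cell genes among them. The smallest adjusted p over genes with limma was then 0.30, and 858 genes had an unadjusted p under 0.05. Over the 8 called lists and their alternatives, 112 values kept direction and call, 24 lost the call and 0 turned. Apart from single arrays left out, medians that moved over 1.5 times without losing the call were 0.13 for cell cycle genes with the authors' table and 0.12 without background correction, 0.16 for interferon genes without background correction, and -0.24 for citrate cycle and 0.06 for unfolded protein response genes with median centring. Of the 21 lists not called, 9 passed under at least 1 alternative, among them oxidative phosphorylation in 5 (median -0.21 with median centring), ribosomal protein genes in 5 and satellite cell genes in 2. For the named genes, 443 values kept direction without a call, 9 changed sign and 1 passed. Dim probes were limited by signal over background: without background correction the log2 fold changes of Kcnq5, Pvr and Nfkbib were -1.18, 0.67 and -0.34. When 1 array was left out they ran from -3.27 to -2.18, from 1.39 to 2.28 and from -1.10 to -0.89. The seed site test and the slide block were not run.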

Other observations

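All tests in this part were chosen after the data were seen. Genes on chromosome 7 stood out among those at an unadjusted p under 0.01. Of 151 such genes 25 lay on chromosome 7, or 16.6%, where the chromosome holds 7.65% of tested genes. The X chromosome held 11, or 7.28%, against 3.06% of tested genes (Fisher's exact test, adjusted p = 0.066). Besides Psmd8, Pvr, Apoe, Nfkbib, Klk1b22, Ptov1, Prpf31 and 3300002P13Rik the chromosome 7 genes include Mrps12, a mitochondrial ribosomal protein gene, with a log2 fold change of 0.87, Lgals4, a galectin gene, with 1.05, and Bcat2, a branched-chain aminotransferase gene, with -0.81. Of the 25, 16 lay among the first 249 of 747 tested genes in chromosomal order. On linear normalized intensity, mdx sample 3 lay at 0.52 of the way from the other mdx samples to the miR-206 KO mdx mean for Psmd8, at 0.58 for Pvr, at 0.60 for Lgals4 and at 0.53 for Prpf31, 4 genes picked for lying near the middle. Over the 25 genes the median place was 0.27, with a range from -0.25 to 0.78 and 12 genes between 0.25 and 0.75. For mdx sample 1 the median was -0.26, with 5 genes in that range and up to 0.47, and for mdx sample 2 it was -0.14, with 3 genes.

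A gain or loss of a single stretch holding all of these genes would move them one way, but 44% of them went in the less frequent direction. That share pools the whole chromosome, so it cannot tell for shorter stretches. In chromosomal order the genes from Klk1b22 to Car11 were all lower and those from Fan1 to Adam8 all higher. Directions were mixed among the genes before Klk1b22. A gain or loss of shorter stretches was not tested. A candidate explanation is that the groups differ in strain DNA on chromosome 7, since the labels give a mixed background. The excess itself (Fisher's exact test, adjusted p = 0.0036 over 20 chromosomes, genes not being independent) restates what was noticed and is no evidence for this explanation. The share was at most 12.5% in the other 9 splits of the arrays, and the excess passed in 5 of 6 settings, and not without the detection filter (adjusted p = 0.18, over a range from 0.0013 across settings), but at an unadjusted p under 0.001, with 7 to 17 genes, it passed in 0 of 6 (lowest adjusted p = 0.058). No genotype of the background was measured, so an effect of miR-206 on these genes and an effect of strain DNA stay open. Chance and other differences between the samples were not excluded either.

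Higher macrophage genes may reflect a lower share of muscle RNA, which would raise markers of other cell types alike. The macrophage score minus that of 24 endothelial and smooth muscle genes was -0.53 ± 0.30 in mdx and 0.53 ± 0.44 in miR-206 KO mdx (SD, n = 3). The difference was 1.07, with a 95% interval of 0.22 to 1.92 (exact permutation p = 0.1, the smallest possible). Because the macrophage list was picked for its large shift in these arrays, the interval overstates the evidence and does not settle that cause. The 24 genes themselves shifted by -0.09, so no rise of these markers was seen. Over the arrays left out the endothelial median ran from -0.26 to 0.07. The 10 splits of 3 arrays against 3 are too few to test chance: the macrophage median was 1.02 and at most 1.17 in another split (2 of 10 splits as large, the real one included), called lists 8 against 13 (4 of 10, likewise), and genes at an unadjusted p under 0.05 were 662 against 1429 (2 of 10, likewise). The split with 1429 genes, picked as the largest of the 10, puts mdx sample 1 with miR-206 KO mdx samples 1 and 3. It gave 0 genes at an adjusted p under 0.05. In a principal component analysis of the tested genes, the axis of largest variation (35.5% of variance) parted the arrays as this split does. On it mdx sample 1 and miR-206 KO mdx samples 1 and 3 lay at -7.78, -21.79 and -16.83. The others, mdx samples 2 and 3 and miR-206 KO mdx sample 2, lay at 22.71, 12.04 and 11.65. The largest variation among the arrays therefore did not follow genotype, and its cause was not tested. An effect of miR-206 loss on macrophage content and spread between animals in the stage of muscle damage stay open.

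The Kcnq5 difference may come from DNA of another strain kept around the deleted gene. Of the other 24 measured flanking genes 0 had an unadjusted p under 0.01, against 1.54% of genes elsewhere (one-sided Fisher's exact p = 0.69), and so few genes cannot tell. A variant under the probe and an effect of the deletion on this transcript were not tested. Over all probes, 24 were detected on every mdx array and no miR-206 KO mdx array, and 75 the other way round.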
